A study of Neotoma lepida with 16 samples.

How the data were processed

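Liver RNA of 16 desert woodrats (Neotoma lepida) was measured on 16 two-colour Agilent rat arrays, 1 array per animal. The red dye (Cy5) carried the RNA of 1 animal and the green dye (Cy3) carried an equimolar pool of the RNA of all 16 animals, and no array had the dyes exchanged. Each array therefore reports a gene's level in 1 animal relative to the average animal of the study, and a dye effect that is alike on all arrays drops out of a difference between groups. The arrays carry rat probes, so a woodrat transcript that differs in sequence from its rat counterpart gives a weaker signal. The probes were not aligned to woodrat transcripts here, and sequence differences between the populations were not examined. Whether probes of closely related genes measured separate woodrat transcripts is therefore not known. No statement is made about the level of one gene against another. Gene symbols are those of the array design, and some have since been renamed (Hspca is now Hsp90aa1, Hspcb Hsp90ab1, Ass Ass1, Arntl Bmal1, Dci Eci1 and Xlkd1 Lyve1). Genome positions were not used.

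The deposited scanner files hold, per spot, the mean signal and the median local background of both dyes, in linear units of intensity, as written by Agilent Feature Extraction 9.1.3.1. The deposited files also hold processed signals, again a linear intensity, in which the software subtracted background, removed spatial trends, balanced the dyes by LOWESS and replaced very dim values by surrogates. A deposited log10 ratio of red over green is computed by the software from these processed signals. The deposited series values are log2 ratios of the processed red over the processed green signal, animal over pool, with no further centring: over all probe spots they differed from that ratio by at most 5e-10.

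The mean and background signals were read again and analysed in R 4.3.3 with limma 3.58.1. Background was corrected by the normexp method with an offset of 50, and each array was normalised by loess with control spots and outlier spots given no weight. The offset is added to both signals and draws ratios of dim genes towards 0. The median red signals of the arrays lay between 71.2 and 121.7 before correction. Fold values and counts of genes that differed at least 2-fold therefore hold for this offset. Spots that the software marked as non-uniform or as population outliers were left out. Of 45018 spots per array, 1639 were controls and 43379 carried 41012 distinct probes for 35561 genes or transcripts. Replicated probes were averaged. A probe was kept when its red signal was well above background on at least 4 of the 16 arrays, and a gene was represented by its brightest kept probe. This left 26472 genes, of which 10644 had a gene symbol and 15828 were known only as transcript tags or predicted loci. Of the genes tested, 3018 had more than 1 kept probe.

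The design crossed 2 populations with 2 diets, with 4 animals in each group. One linear model with the 4 group means and an additive sex term was fitted by limma to all 16 arrays, since the 4 Mojave animals on creosote were all male and each other group held 2 males and 2 females. The residual degrees of freedom were 11 and the prior degrees of freedom 4.03. Differences were tested by the moderated statistics of limma, two-sided, with Benjamini-Hochberg adjustment over the 26472 genes and a threshold of 0.05. The contrasts were the diet effect in each population (creosote minus juniper), the population effect on each diet (Mojave minus Great Basin), their interaction (the Mojave diet effect minus the Great Basin diet effect), and both effects averaged over the other factor. Values are log2 differences with their standard errors from the model. The number of arrays limits the precision: the median standard error was 0.089 for the diet effect in Great Basin, 0.096 in Mojave, and 0.131 for the interaction.

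The 39 gene lists, the contrasts, the tests, the alternatives and the rule for naming genes were fixed before the data were examined, except where the text says otherwise. The lists covered P450 families 1 to 3 and 4, UDP-glucuronosyltransferases, glutathione S-transferases, sulfotransferases, carboxylesterases and epoxide hydrolases, carbonyl-reducing and aldehyde-oxidising enzymes, other conjugating enzymes, drug transporters, targets of NRF2, AHR, and CAR and PXR, cholesterol synthesis, lipogenesis, fatty acid oxidation, bile acids, gluconeogenesis and glycogen, urea cycle and amino acid catabolism, acute phase, endoplasmic reticulum stress, heat shock, p53 targets, proliferation, metal and iron handling, the circadian clock, ribosomal proteins, oxidative phosphorylation, the proteasome, complement and coagulation, and sex-biased liver genes. Marker lists stood for Kupffer cells, stellate cells, endothelium, cholangiocytes, lymphocytes, erythroid cells, neutrophils, hepatocytes, and pancreas and intestine. Each list with at least 5 measured genes was tested in each contrast by camera with a preset correlation of 0.01, two-sided, adjusted over the 38 lists tested. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. The camera test was also run with a correlation estimated for each list, and fry was run as a test that looks at a list without comparing it with other genes.

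Named genes followed a rule with 3 parts. The first part took, in each contrast, the 10 symbols with the largest positive and the 10 with the largest negative difference among those past the threshold, or all where fewer passed, or the 5 with the smallest p where none passed. The second part took up to 4 members of each list with the smallest adjusted p, or up to 2 with the largest difference where none passed. The third part took the subfamilies Cyp1a, Cyp2a, Cyp2b, Cyp3a, Gsta and Gstm and the genes Nqo1 and Cyp7a1 whatever their values.

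The file headers placed the arrays on 4 slides of 4 arrays each, and each slide carried 1 animal of each group. Position on the slide went with the group: Great Basin creosote lay at position 1, Mojave creosote at 2, Mojave juniper at 3 and Great Basin juniper at 4 on all 4 slides. Differences within each slide are given beside some of the results only, and the counts are given with slide as a block too. On single slides some named results ran against their direction. In the Great Basin diet effect these were Mbl1 (-0.06, slide 4), Cyp2b3 (0.20, slide 2) and the medians of fatty acid oxidation (0.04, slide 4) and stellate markers (-0.01, slide 1). In the Mojave diet effect they were Aldh5a1 (-0.05, slide 2), Hspca (0.03, slide 3), Xlkd1 (-0.06, slide 2) and Cyp3a18 (0.05, slide 1), and Ela1 was at 0.00 on slide 4. For the population effect on juniper they were the medians of the urea cycle (-0.08 and -0.06, slides 2 and 4), oxidative phosphorylation (0.05, slide 4) and complement lists (0.01, slide 2). Correlations between arrays after removal of the group means were compared for arrays with the same replicate number and with the same slide, and arrays were checked for duplicates: the highest correlation between arrays of a group was 0.546 and no arrays were identical.

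The model fit and the list test were run on simulated log2 ratios of the same size. With 4 animals per group, planted differences of 1 on the log2 scale were recovered in 100% of 67 genes for the Great Basin diet effect, 97.0% for the Mojave diet effect, 97.0% for the population effect on creosote and 92.5% for the interaction. At a planted difference of 0.5 these shares were 55.2%, 62.7%, 71.6% and 38.8%. Outside all planted genes, of 26472 simulated, false calls numbered 9, 6, 16 and 17. A planted shift of -0.5 in the proteasome genes was called in that list and in 0 of the others. The simulated genes had the residual spread of the real ones, alike in all groups, and varied independently of each other. The simulation therefore does not show how many genes or lists are falsely called where genes vary together. Nor does it show the recovery or the false calls where 1 group varies more than another.

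The alternatives were the processed signals, no background subtraction, an offset of 0, median centring in place of loess, quantile and scale normalisation between arrays, the Cy5 channel alone, the series values, no filter on dim probes, a filter on all 16 arrays, the mean of all probes of a gene, no sex term, male animals alone, only the 8 arrays compared, replicate number and slide as blocks, eBayes with trend and robust settings, array weights, a threshold of 1 on the log2 difference, and leaving out each animal in turn. Leaving out the dimmest slide, and the list tests with blocks or without that slide, were added after the data were seen. Ways of dividing the same arrays into groups of the same sizes were counted, the real one included. All 35 were taken for a comparison of 4 with 4 animals. For the averaged contrasts and the interaction there were 100, drawn at random apart from the real one. Animals were exchanged within a population for the averaged diet effect and the interaction, and within a diet for the averaged population effect.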

Results

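Desert woodrats of 2 populations, from the Great Basin and the Mojave desert, were kept on rabbit chow for 3 months and then fed chow with rising amounts of either creosote bush or juniper for 5 days. The trial asked how the liver responds to plant diets with different secondary compounds, and whether the populations respond differently. Each of the 4 groups held 4 animals. No group stayed on chow alone, so a gene that was higher on creosote can equally be described as lower on juniper. Words such as rose and fell describe creosote relative to juniper, and which of the diets changed a gene cannot be told. The share of probes well above background in the animal channel ranged from 46.4% to 76.2% over the 16 arrays. Its mean was 60.6% ± 10.2 (SD, n = 4) in Great Basin creosote, 65.2% ± 11.2 (SD, n = 4) in Great Basin juniper, 65.0% ± 9.45 (SD, n = 4) in Mojave creosote and 66.5% ± 12.4 (SD, n = 4) in Mojave juniper. The arrays of slide 1 were dimmer, at 49.2% on average, than those of the other slides, at 66.0%, 70.4% and 71.7%, and slide 1 held 1 animal of each group. On all 4 slides the creosote arrays lay at positions 1 and 2 and the juniper arrays at positions 3 and 4. Great Basin arrays lay at the outer positions 1 and 4 and Mojave arrays at the inner positions 2 and 3. The design alone therefore separates neither diet nor population from position, and position was not weighed for the population results. The first principal component of the genes with a value on all 16 arrays carried 27.4% of the variance. It was negative for each creosote array (-28.74 to -5.66) and positive for each juniper array (10.5 to 22.48).

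In Great Basin animals, the livers on creosote held more transcript of the interleukin-1 decoy receptor Il1r2 than those on juniper, by 3.37 ± 0.33 on the log2 scale (SE, n = 4 per group, adjusted p = 7.18e-05), a 10.3-fold difference. The fatty acid elongase Elovl6 was higher by 2.67 ± 0.27 (6.36-fold), the activin antagonist follistatin (Fst) by 2.21 ± 0.48 and the amylase genes Amy2 and Amy1 by 1.89 ± 0.25 and 1.59 ± 0.22. The apolipoprotein gene Apoa4 was lower on creosote by -2.42 ± 0.23 (SE, n = 4 per group, adjusted p = 4.52e-05), a 5.34-fold difference. Lower as well were 3 cytochromes P450 of the phenobarbital-inducible 2b subfamily, Cyp2b15 (-1.86 ± 0.28), Cyp2b13 (-1.65 ± 0.28) and Cyp2b2 (-1.36 ± 0.21), with the haem-synthesis enzyme Alas1 (-1.55 ± 0.35) and cytochrome b5, Cyb5 (-1.52 ± 0.14). The within-slide differences ranged from 2.66 to 4.21 for Il1r2, from 1.98 to 3.26 for Elovl6 and from -3.36 to -1.62 for Apoa4, with the same direction on 4 of 4 slides.

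The other genes named by size in this comparison were, on the higher side, the calcium pump Atp2b2 (2.01), the proteinase inhibitor Mug2 (1.87), Acmsd of tryptophan catabolism (1.82), the retinoic acid hydroxylase Cyp26a1 (1.66) and the clock activator Arntl (1.61). On the lower side stood the coat protein gene Copz2 (-1.83), the clock repressor Per2 (-1.83), the liver glycogen synthase Gys2 (-1.56) and Cyp2c7 (-1.48). A second probe did not show the difference for Elovl6 (-0.07), Amy2 (0.09), Copz2 (-0.04) and Cyp2b15 (0.15), for Mug2 it was smaller (0.34), and for Gys2 it pointed the other way (1.07). The second probes of Atp2b2 (1.91) and Fst (1.45) and 3 further probes of Cyp2b2 (-0.23, -0.96 and -2.17) showed the same direction, the first of the 3 with a much smaller value, and that of Cyp2b13 was smaller too (-0.44). Of 2 further probes of Cyp2c7, 1 did not show the difference (-0.11) and 1 did (-1.90). Leaving out 1 animal ended the call of 3 of these genes. Fst was lost without Great Basin creosote 1 or 3 or juniper 1 or 2 (adjusted p = 0.0578, 0.0532, 0.0615 and 0.0514), Mug2 without creosote 1 or juniper 1, 3 or 4 (adjusted p = 0.0874, 0.0735, 0.0666 and 0.0895), and Alas1 without creosote 1 or 4 or juniper 1 or 3 (adjusted p = 0.0762, 0.0541, 0.0683 and 0.0564).

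The subunits of the proteasome, the complex that degrades ubiquitin-tagged proteins, fell together on creosote in Great Basin animals. Of 39 measured members, 28 were lower, 0 were higher and 11 did not pass, or 31 lower adjusted over the list alone. The median difference was -0.68 and the camera test gave an adjusted p of 4.75e-24, with an adjusted p = 0.00199 with an estimated correlation. Examples were the catalytic subunit Psmb6 (-0.92 ± 0.09), the core subunit Psma5 (-0.90 ± 0.09) and the regulatory subunits Psmd12 (-1.09 ± 0.11) and Psmd2 (-0.80 ± 0.08). The list median was lower on each of the 4 slides, between -0.69 and -0.54. Heat shock proteins fell too, with 7 of 13 lower and 0 higher (9 lower and 1 higher adjusted over the list alone). Their median was -0.67 and camera gave an adjusted p of 1.12e-07, or adjusted p = 0.0594 with an estimated correlation. Among them were the chaperones Hspcb (-0.78), Dnaja1 (-0.99), Hspb1 (-1.22) and mitochondrial Hspd1 (-0.67), and the slides gave medians between -1.07 and -0.37.

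Genes of the urea cycle and of amino acid catabolism rose on creosote in Great Basin animals, with 11 of 22 higher and 0 lower, or 15 higher adjusted over the list alone. The median was 0.72, between 0.46 and 0.74 on the slides, and camera gave an adjusted p of 5.19e-13 (adjusted p = 0.00199 with an estimated correlation). They included Bhmt of methionine metabolism (1.57 ± 0.15), the first urea cycle enzyme Cps1 (1.03 ± 0.12), the histidine-degrading Hal (1.23 ± 0.15) and argininosuccinate synthase, Ass (0.65 ± 0.09). Markers of hepatocytes moved the same way, with 5 of 15 higher and 0 lower (8 higher adjusted over the list alone). The median was 0.63, and camera gave an adjusted p of 1.12e-07 (adjusted p = 0.00199 with an estimated correlation). Of these 15 markers, 4 stood in another list as well, Cps1 and Tat among them, and further members past the threshold were the secreted proteins Ahsg (0.86) and Ambp (0.63). Complement and coagulation genes were higher in 3 of 30 and lower in 0 (4 higher adjusted over the list alone), with C5 at 0.88 and the lectin Mbl1 at 1.27. For this list camera gave an adjusted p of 2.61e-06, or adjusted p = 0.0663 with an estimated correlation. The call of Mbl1 was lost without Great Basin juniper 1 (adjusted p = 0.0619) or juniper 4 (adjusted p = 0.0626).

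Of the drug-metabolising P450s of families 1 to 3, more were lower than higher on creosote in Great Basin animals, and most did not pass. Of 34 measured, 11 were lower, 1 higher and 22 not past the threshold (12 lower and 2 higher adjusted over the list alone). The adjusted p was 0.0012 by camera, and an adjusted p = 0.0594 with an estimated correlation. By their brightest probes all 4 measured Cyp2b genes were lower, Cyp2b3 the least (-0.57), and so were 3 of 5 Cyp3a genes, among them Cyp3a3 (-1.18 ± 0.17) and Cyp3a11 (-0.54 ± 0.08). A second probe of Cyp2b15 did not show the fall (0.15). The call of Cyp2b3 was lost without Great Basin creosote 1 or 4 or juniper 1 or 3 (adjusted p = 0.0731, 0.074, 0.108 and 0.0993), and that of the third Cyp3a gene, Cyp3a18 (-0.40), without juniper 2 or 4 (0.0602 and 0.0546). None of 3 Cyp2a genes passed, nor did Cyp1a2 (0.26, adjusted p = 0.778), the only Cyp1a gene tested. The probe of Cyp7a1, the bile acid synthesis enzyme, was not above background on enough arrays to be tested. The targets of the drug-sensing receptors CAR and PXR included 7 of 17 lower and 1 higher (7 lower and 3 higher adjusted over the list alone), without a call of the list by camera (adjusted p = 0.392). The member that was higher was the gene of the receptor CAR itself, Nr1i3 (0.67 ± 0.11). NRF2 targets, which serve antioxidant defence, fell in 4 of 20 and rose in 0 (7 lower adjusted over the list alone). Examples were Ugdh at -1.11, glutathione reductase Gsr at -0.78 and Prdx1 at -0.74. Camera gave this list an adjusted p of 0.0111, or adjusted p = 0.147 with an estimated correlation and 0.0512 with median centring, so it was lost in both. Nqo1 was at -0.62 (adjusted p = 0.112), 0 of 3 Gsta genes passed, and 1 of 6 Gstm genes did, Gstm2 at 1.30. Gstm2 was lost without Great Basin creosote 1 or 3 or juniper 1, 2 or 4 (adjusted p = 0.0762, 0.0503, 0.0606, 0.0656 and 0.0503).

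In lipid and carbohydrate metabolism, lipogenic genes of Great Basin animals were higher on creosote in 5 of 18 and lower in 1 (6 and 2 adjusted over the list alone). They included the regulator Srebf1 at 1.45 ± 0.19, the desaturase Scd2 at 1.10 ± 0.15 and the carboxylase Acaca at 1.14 ± 0.18. Camera gave an adjusted p of 0.0184, or adjusted p = 0.0663 with an estimated correlation. Fatty acid oxidation genes and targets of PPARA fell in 6 of 21 and rose in 0 (8 lower and 1 higher adjusted over the list alone), among them Dci (-0.77) and the hormone gene Fgf21 (-0.83). Their adjusted p was 0.000289 by camera and adjusted p = 0.105 with an estimated correlation. Genes of gluconeogenesis and glycogen were higher in 4 of 15 and lower in 1 (4 and 1 adjusted over the list alone), with Ppp1r3c at 1.53, Tat at 1.41 and glucose-6-phosphatase G6pc at 1.36. Camera called this list at an adjusted p of 0.0345, with an adjusted p = 0.105 with an estimated correlation, 0.145 without slide 1 and 0.0519 with replicate number as a block. Stellate cell and fibroblast markers were higher in 1 of 15, Rgs5 at 1.23, and lower in 0 (1 higher adjusted over the list alone). Their adjusted p was 0.03 by camera, and an adjusted p = 0.42 with an estimated correlation.

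The remaining lists were not called by camera in Great Basin animals. Among enzymes and carriers of foreign compounds, the members past the threshold were 0 of 8 P450s of family 4 (adjusted p = 0.392), 0 of 11 UDP-glucuronosyltransferases (0.488), 1 higher and 1 lower of 19 glutathione S-transferases (0.63). They were 0 of 9 sulfotransferases (0.249) and 0 of 6 carboxylesterases and epoxide hydrolases (0.0778). They were 0 of 37 carbonyl-reducing and aldehyde-oxidising enzymes (0.931), 1 higher of 7 other conjugating enzymes, the methyltransferase Gnmt at 1.14 ± 0.11 (0.31). Also past were 2 higher of 35 drug transporters, Slc22a12 at 0.37 and Abcc5 at 0.41 (0.924), and 0 of 6 AHR targets (0.63). Slc22a12 was lost without Great Basin creosote 1 or 4 or juniper 1 or 4 (adjusted p = 0.0759, 0.053, 0.0681 and 0.063). Abcc5 was lost without any of 12 animals, all except Mojave creosote 1 and 2 and Mojave juniper 1 and 3, with adjusted p values up to 0.143. These counts were the same adjusted over the list alone, except 2 higher for the other conjugating enzymes. Of 15 clock genes 1 was higher and 3 lower (1 and 4 adjusted over the list alone), Arntl on the higher and Per2, Per3 (-0.68) and Hlf (-0.82) on the lower side (list 0.229). Per3 was lost without Great Basin creosote 1 or 4 or juniper 1 or 2 (adjusted p = 0.0905, 0.0655, 0.0682 and 0.0864), and Hlf without these (0.0969, 0.0711, 0.104 and 0.0892) or juniper 4 (0.0738). The members past the threshold were 0 of 21 for cholesterol synthesis (0.931), 1 of 15 for bile acids (0.392), 1 of 20 for acute phase (4 adjusted over the list alone, 0.107). There were 0 of 18 for endoplasmic reticulum stress (0.31), 2 of 9 p53 targets, in opposite directions (0.488), 0 of 21 for proliferation (0.488), 0 of 13 for metal and iron handling (1 adjusted over the list alone, 0.56). Likewise 1 of 72 ribosomal proteins (0.924), 2 of 56 for oxidative phosphorylation, in opposite directions (0.488), and 1 of 14 sex-biased genes (2 adjusted over the list alone, 0.56) passed. The median and mean of the p53 list differed in sign (0.16 and -0.02). Among these members, the bile acid gene Slc27a5 (0.79) was lost without Great Basin creosote 3 or any Great Basin juniper animal (adjusted p up to 0.0718), and Mdm2 of the p53 list without creosote 1 or juniper 3 (0.0504 and 0.0503). Of the other marker lists, 1 of 12 Kupffer cell genes passed, Cd14 at -0.54 (0.931), 1 of 11 endothelial genes, Xlkd1 at 0.56 (0.1), and 1 of 14 pancreas and intestine genes (0.5). In the rest 0 passed: 0 of 9 cholangiocyte (0.63), 0 of 11 lymphocyte (0.31), 0 of 9 neutrophil (0.56) and 0 of 4 erythroid genes, the last without a list test.

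In total, limma called 1052 of 26472 genes in the Great Basin diet comparison, 547 higher and 505 lower on creosote, of which 122 differed at least 2-fold. The balance of the directions depended on the method, with 733 of 1154 calls higher (63.5%) with median centring and 610 higher and 899 lower (40.4% higher) with the Cy5 channel alone. A fit with slide as a block called 1048. Of 270 further probes of called genes, 214 (79.3%) had the direction of the brightest probe. At an unadjusted p under 0.05 by limma, 114 had the same direction and 8 the opposite one. The count depended on single animals: it was 661 without creosote 1, 627 without juniper 1 and 650 without juniper 4. It was 386 without the 4 dim arrays of slide 1 and 152 in male animals alone.

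**Figure D1:**
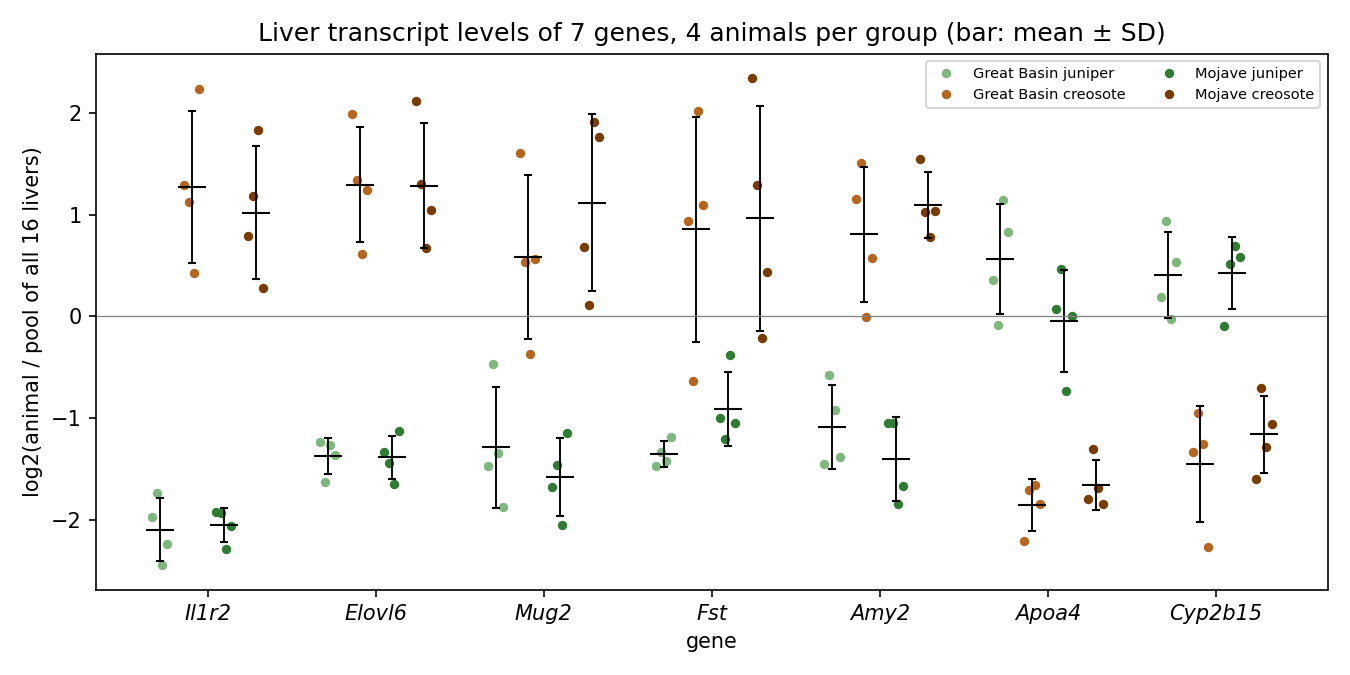
Liver transcript levels of the 7 genes that were among those with the largest differences in both diet comparisons: the vertical axis is the log2 ratio of each animal to the pool of all 16 livers, points are the 4 animals of a group and bars the mean ± SD, and Il1r2, Elovl6, Mug2, Fst and Amy2 had higher means on creosote in both populations and Apoa4 and Cyp2b15 lower ones.

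In Mojave animals, the livers on creosote also held more Il1r2, by 3.13 ± 0.36 (SE, n = 4 per group, adjusted p = 0.000195), an 8.77-fold difference, and more Elovl6 (2.53 ± 0.29, 5.77-fold), Mug2 (2.64 ± 0.47) and Amy2 (2.23 ± 0.27). The desaturase Scd2 was higher by 1.88 ± 0.16 and the complement regulator Cfi by 1.78 ± 0.34. The call with the smallest p was that of the histone chaperone Asf1a, lower on creosote by -1.81 ± 0.09 (SE, n = 4 per group, adjusted p = 6.06e-08), and its second probe gave -1.40. Apoa4 was lower by -1.82 ± 0.24, Cyp2b15 by -1.57 ± 0.30 and Cyp3a3 by -1.49 ± 0.19. Within the slides, Il1r2 differed by 2.35 to 4.12, Asf1a by -2.06 to -1.50 and Apoa4 by -1.87 to -0.95, with the same direction on 4 of 4 slides.

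Further genes named by size in the Mojave comparison were, on the higher side, Bex4 (2.69), Fst (2.16), the nuclear envelope protein emerin, Emd (2.01), and the growth factor binding protein Igfbp3 (1.92). On the lower side were the NF-kappaB pathway kinase Chuk (-1.95), the actin-binding Pfn2 (-1.69), the lectin Lgals8 (-1.55), the elongase Elovl2 (-1.54), Cyp2d10 (-1.50) and the proteasome subunit Psmd13 (-1.49). Second probes were near 0 for Elovl6 (0.03), Mug2 (0.08) and 1 of the 2 others of Scd2 (-0.05, the other 2.50), smaller for Amy2 (0.73), and alike for Igfbp3 (1.81). The second probe of Cyp2b15 did not show the fall (0.31, opposite in sign). The second probe of Elovl2 had a smaller difference (-0.46). Fst was lost without Mojave juniper 2 (adjusted p = 0.0523) and differed by 0.17 to 3.34 over the slides, and Chuk was lost without Mojave juniper 1 (adjusted p = 0.0641). The call of Igfbp3 was lost without any of 10 animals: Great Basin juniper 1, 2, 3 and 4 (adjusted p = 0.0518, 0.0613, 0.0615 and 0.0581), Mojave creosote 1, 3 and 4 (adjusted p = 0.11, 0.0907 and 0.0777) and Mojave juniper 1, 2 and 3 (adjusted p = 0.145, 0.16 and 0.0759).

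Proteasome genes fell on creosote in Mojave animals as well, with 25 of 39 lower and 0 higher (28 lower adjusted over the list alone). The median was -0.54 and camera gave an adjusted p of 1.82e-16 (adjusted p = 0.0271 with an estimated correlation). Psma1 (-1.18 ± 0.12), Psmd5 (-1.10 ± 0.13), Psma6 (-1.08 ± 0.10) and Psmd2 (-0.96 ± 0.09) were the members with the smallest adjusted p, and the slide medians lay between -0.63 and -0.48. Heat shock proteins fell in 7 of 13 and rose in 0 (8 lower adjusted over the list alone), with Hspd1 at -1.09, Hspca at -1.10 and Hspcb at -0.60. Their median was -0.60, with slide medians between -0.64 and -0.23, and camera gave an adjusted p of 0.000716, or adjusted p = 0.209 with an estimated correlation. Genes of the urea cycle and amino acid catabolism rose in 9 of 22 and fell in 0 (11 higher adjusted over the list alone), with the serine dehydratase Sds at 1.41, Cth at 1.04, Hal at 0.96 and Tat at 0.96, and slide medians between 0.12 and 0.54. Camera gave this list an adjusted p of 5.77e-05, or adjusted p = 0.0542 with an estimated correlation. Hepatocyte markers rose in 6 of 15 and fell in 0 (8 higher adjusted over the list alone), with albumin, Alb, at 1.63 and Ambp at 0.59. Camera gave them an adjusted p of 0.00264 (adjusted p = 0.0542 with an estimated correlation). Complement and coagulation genes rose in 4 of 30 and fell in 0 (10 higher adjusted over the list alone), among them C5 (0.91) and protein C, Proc (0.60). Camera gave an adjusted p of 5.77e-05, and an adjusted p = 0.151 with an estimated correlation. With median centring in place of loess the urea cycle, hepatocyte and complement lists were not called in Mojave animals (adjusted p = 0.12, 0.182 and 0.12).

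Of the P450s of families 1 to 3, 9 of 34 were lower on creosote in Mojave animals and 2 were higher (11 and 2 adjusted over the list alone). The list was not called by camera (adjusted p = 0.244). Lower were 3 of 4 Cyp2b genes, 3 of 5 Cyp3a genes, Cyp2d10 and Cyp2d22 (-1.42). Of the Cyp2a genes 1 of 3 passed, and it was higher, Cyp2a3a at 1.05. It was lost without Mojave creosote 1 or 2 or juniper 3 or 4 (adjusted p = 0.0574, 0.0738, 0.0557 and 0.0609), and the third Cyp3a gene, Cyp3a18, without juniper 1 or 2 (0.0711 and 0.0572). Cyp1a2 was at -0.20 (adjusted p = 0.835). NRF2 targets fell in 7 of 20 and rose in 0 (9 lower adjusted over the list alone), with Ugdh at -1.05, Gsr at -0.85 and thioredoxin, Txn1, at -0.97. Camera gave an adjusted p of 0.00438, and an adjusted p = 0.151 with an estimated correlation. The CAR and PXR targets held 6 of 17 lower and 1 higher (10 and 1 adjusted over the list alone), with the P450 reductase Por at -1.19 and Nr1i3 at 0.82. The list was not called (adjusted p = 0.0925). Among the glutathione S-transferases 3 of 19 were higher and 2 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.546). Gstm genes passed in opposite directions, with Gstm5 at 1.65 and Gstm4 at -1.10 as 2 of 6, and 0 of 3 Gsta genes passed. The call of Gstm5 was lost without Mojave creosote 1 or 4 or juniper 1 or 4 (adjusted p = 0.0824, 0.0766, 0.114 and 0.0638).

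Lipogenic genes rose on creosote in Mojave animals in 5 of 18 and fell in 1 (7 and 1 adjusted over the list alone), with Acaca at 1.26 and Srebf1 at 1.29. Camera gave an adjusted p of 0.00629, and an adjusted p = 0.0542 with an estimated correlation. Fatty acid oxidation genes fell in 3 of 21 and rose in 0 (6 lower adjusted over the list alone), Dci (-1.03) and the carnitine carrier Slc25a20 (-0.87) among them. The adjusted p was 0.0179 by camera, 0.223 with no sex term and adjusted p = 0.342 with an estimated correlation. Gluconeogenic and glycogen genes rose in 5 of 15 and fell in 1 (5 and 1 adjusted over the list alone), with G6pc at 1.68 and Fbp1 at 0.79. Here camera gave an adjusted p of 0.0377, and an adjusted p = 0.151 with an estimated correlation. Proliferation genes fell in 3 of 21 and rose in 0 (4 lower adjusted over the list alone), with the replication helicase subunit Mcm2 at -1.11 and cyclin D1, Ccnd1, at -1.31. Their adjusted p was 0.000716 by camera, and an adjusted p = 0.342 with an estimated correlation. Ribosomal protein genes were higher in 14 of 72 and lower in 3 (18 and 3 adjusted over the list alone), with Rps3a at 0.76 and Rpl19 at 0.39. Oxidative phosphorylation genes were higher in 7 of 56 and lower in 2 (10 and 3 adjusted over the list alone), with Ndufa6 at -0.72 among the lower. Camera gave these lists adjusted p values of 0.000304 and 0.0154, and adjusted p = 0.342 and adjusted p = 0.209 with an estimated correlation. Over the members measured on all 16 arrays, both lists turned to the lower side with median centring, with medians of -0.251 and -0.099, and so did the medians of lipogenesis (-0.051) and of gluconeogenesis and glycogen (-0.005).

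The lists not called by camera in Mojave animals included 0 of 8 P450s of family 4 (adjusted p = 0.986), 1 lower of 11 UDP-glucuronosyltransferases, Ugt1a2 at -0.93 (0.982), and 1 higher of 9 sulfotransferases, Sult1a1 at 0.79 (0.775). They also included 0 of 6 carboxylesterases and epoxide hydrolases (0.569) and 1 higher and 1 lower of 37 carbonyl-reducing and aldehyde-oxidising enzymes (0.775). Among the latter, Cbr1 at -1.45 was lost without Mojave juniper 2 (adjusted p = 0.0614). Of 7 other conjugating enzymes 2 were higher, Gnmt at 1.27 ± 0.11 and Glyat at 0.90 (0.626). Of 35 drug transporters 1 was higher, Abcc4 at 0.25, and 2 were lower, Slc22a5 at -0.86 and Abcc3 at -0.69 (0.602). Abcc3 was lost without any of 12 animals, all except Great Basin creosote 3, Mojave creosote 2 and 3 and Mojave juniper 3 (adjusted p up to 0.131). Abcc4 was lost without any of 13, all except Great Basin creosote 3 and 4 and Mojave creosote 2 (adjusted p up to 0.102). Of 6 AHR targets 1 was lower, Nqo1 (0.848). The difference in Nqo1 was -0.76 ± 0.22 (adjusted p = 0.0402), and its call was lost without any of 11 animals, with adjusted p values from 0.0502 without Great Basin creosote 2 to 0.138 without Mojave juniper 2. It was lost as well without Great Basin creosote 1 and 3 (0.0542 and 0.0512), Great Basin juniper 1 and 4 (0.0556 and 0.0524), Mojave creosote 2 and 3 (0.101 and 0.0861) and Mojave juniper 1, 3 and 4 (0.0778, 0.0534 and 0.0768). Members past the threshold were 1 of 21 for cholesterol synthesis (0.98), 1 of 15 for bile acids, Slc27a5 at 0.99 (0.775), 3 of 20 for acute phase (0.163). They were 1 of 18 for endoplasmic reticulum stress (0.393), 1 of 9 p53 targets, Gadd45a at -1.27 (0.755), 0 of 13 for metal and iron handling (0.626), 2 of 15 clock genes, in opposite directions (0.755), and 1 of 14 sex-biased genes (0.602). Of the marker lists, 0 of 12 Kupffer (0.775), 0 of 15 stellate (0.301), 0 of 9 cholangiocyte (0.775), 0 of 11 lymphocyte (0.626), 0 of 9 neutrophil (0.301) and 0 of 4 erythroid genes passed. Past the threshold were 2 of 11 endothelial genes in opposite directions, Xlkd1 at 0.56 and Tie1 at -0.31 (0.775), and 2 of 14 pancreas and intestine genes (0.139). Tie1 was lost without any of 14 animals, all except Great Basin creosote 4 and Mojave creosote 1 (adjusted p up to 0.144), and Ela1 of the last list (0.59) without Mojave creosote 1 or 3 or juniper 1 (0.0535, 0.0702 and 0.125). Other members counted here were lost without single animals as well, up to an adjusted p of 0.179 for Aldh5a1, 0.118 for Cyp51, 0.122 for Fgb and Orm1, 0.0812 for Itih3, 0.0654 for Ddit4, 0.123 for Nfil3, 0.134 for Tef and 0.218 for Cyp2c7. The animal was Mojave juniper 2 for Aldh5a1, Fgb, Orm1, Ddit4 and Cyp2c7 and Mojave juniper 1 for the others. Counts differed when adjusted over the list alone for clock genes (3 higher, 4 lower), endoplasmic reticulum stress (2 higher) and carboxylesterases and epoxide hydrolases (1 lower), among others.

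In total, limma called 2531 of 26472 genes in the Mojave diet comparison, 1014 higher and 1517 lower on creosote, of which 248 differed at least 2-fold. A fit with slide as a block called 2468. Of 688 further probes of called genes, 479 (69.6%) had the direction of the brightest probe. At an unadjusted p under 0.05 by limma, 255 had the same direction and 42 the opposite one. The count was 1617 without Mojave juniper 1 and 1585 without Mojave juniper 2, and the share of calls that were higher fell from 40.1% to 13.7% with median centring and rose to 52.7% with the Cy5 channel alone (577 higher and 517 lower).

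**Figure D2:**
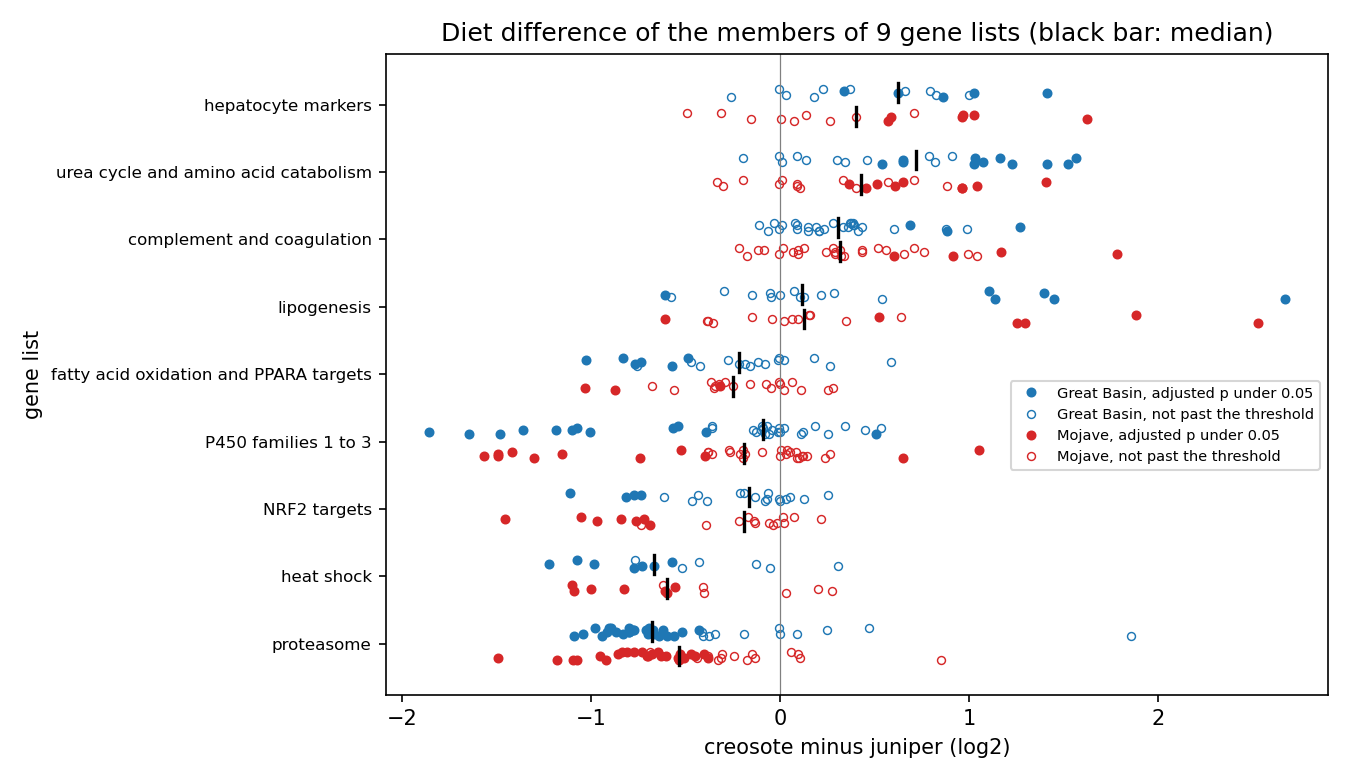
Diet differences of the measured members of 9 gene lists, where the horizontal axis is the log2 difference of creosote minus juniper, each point is a gene, filled points passed an adjusted p of 0.05 and black bars are medians. The proteasome medians were -0.68 in Great Basin and -0.54 in Mojave animals, and the urea cycle medians were 0.72 and 0.43.

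Of the 3036 genes called in either population, 2452 (80.8%) had the same direction in both. Of the genes called in both populations, 248 were higher on creosote in both, 297 were lower in both, and 2 were called in opposite directions. Independent calls would share 20.95 and 28.94. These are no chance level here, since both differences came from 1 fit with 1 estimate of the spread per gene. In both populations the diets also lay on the same opposite sides of the slide. Across all genes, which are not independent replicates, the Pearson correlation of both differences was 0.520. Averaged over the populations, the diet effect was largest for Il1r2 (3.25 ± 0.25, SE, n = 8 per diet), Elovl6 (2.60 ± 0.20) and Mug2 (2.26 ± 0.32) on the higher side and for Apoa4 (-2.12 ± 0.17) and Cyp2b15 (-1.71 ± 0.21) on the lower side. A second probe did not show the difference for Elovl6 (-0.02) and Cyp2b15 (0.23, opposite in sign), and for Mug2 it was much smaller (0.21). Genes named for the averaged effect alone were Hsd17b9 (1.54) and the chromatin protein Baz2a (1.52 ± 0.08, adjusted p = 3.48e-08), both higher. In total 3199 genes were called for the averaged effect, 1510 higher and 1689 lower on creosote, and 2112 without slide 1. With median centring 1118 were higher and 2734 lower (3852), and with the Cy5 channel alone 1314 were higher and 1199 lower. A fit with slide as a block called 3079. In this average the proteasome held 32 of 39 genes lower (33 adjusted over the list alone, camera adjusted p = 1.24e-22, adjusted p = 0.00397 with an estimated correlation) and the urea cycle list 14 of 22 higher (15 higher and 1 lower adjusted over the list alone, adjusted p = 3.16e-10, adjusted p = 0.00413 with an estimated correlation). Camera also called heat shock (9 of 13 lower and 1 higher, 10 and 1 adjusted over the list alone), NRF2 targets (6 of 20 lower, 11 adjusted over the list alone), fatty acid oxidation (9 of 21 lower and 1 higher, as adjusted over the list alone) and complement and coagulation (10 of 30 higher, 14 adjusted over the list alone). The adjusted p values were 2.28e-06, 0.000541, 0.000541 and 2.21e-07, and the calls were lost with an estimated correlation (adjusted p = 0.0686, 0.0686, 0.116 and 0.0529). Calls at adjusted p values from 0.0186 to 0.049 were those of the P450s of families 1 to 3, gluconeogenesis, ribosomal proteins, oxidative phosphorylation, acute phase and stellate markers, lost with an estimated correlation as well (adjusted p = 0.126, 0.0818, 0.499, 0.307, 0.499 and 0.495). Hepatocyte markers held 8 of 15 higher (9 adjusted over the list alone, adjusted p = 2.28e-06, adjusted p = 0.00397 with an estimated correlation) and lipogenesis 6 of 18 higher and 2 lower (7 and 2 adjusted over the list alone, adjusted p = 0.00595, adjusted p = 0.0493 with an estimated correlation). These were the 4 of 14 called lists of the averaged diet effect that held with an estimated correlation, while in the separate populations those that held were the proteasome, urea cycle and hepatocyte lists in Great Basin animals and the proteasome list in Mojave animals.

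The comparison of the populations on the same diet asks whether Mojave animals, which meet creosote bush in their range, differ from Great Basin animals. On creosote, the livers of Mojave animals held less Bhmt, an enzyme that remethylates homocysteine, by -1.40 ± 0.18 (SE, n = 4 per group, adjusted p = 0.0186), less of the syntrophin Sntb1 (-1.15 ± 0.17), the lipid phosphatase Ppap2b (-0.94 ± 0.13) and the semaphorin receptor Plxnb1 (-0.79 ± 0.12). They held more Scd2 (0.95 ± 0.16, adjusted p = 0.0476), Hint2 (0.81 ± 0.12) and the mitophagy receptor Bnip3l (0.70 ± 0.12). A second probe did not show the difference of Bhmt (0.01), Ppap2b (-0.07) or Plxnb1 (-0.15), while 2 further probes of Scd2 gave 1.85 and 0.17. Sequence differences between the populations under these probes were not examined, so a difference in signal need not be one in transcript level. Limma called 19 of 26472 genes, 7 higher and 12 lower in Mojave, and 21 with slide as a block, and camera called 0 of 38 lists. Fry called 0 as well, as did camera with an estimated correlation, but camera called 5 lists with median centring. The count rested on single animals. It was 4 without Great Basin creosote 1, 105 without creosote 2, 473 without creosote 4, 0 without Mojave creosote 1, 224 without Mojave creosote 3 and 54 without Mojave creosote 4. It was 283 when sex was left out of the model, 3127 with median centring and 0 without slide 1 or with the processed signals. With only the 8 arrays compared the count was 3, while on juniper it rose from 3 to 72. The main fit took 1 estimate of the spread per gene for all groups. On the second principal component the creosote groups ran from 3.36 to 27.33 (Great Basin) and -23.85 to 1.57 (Mojave). The juniper groups spread less, from -3.31 to 0.996 and -6.03 to -2.96, but not on the third component. The pooled standard errors may therefore be too small on creosote and too large on juniper. The 7 named genes all lost their call without Mojave creosote 1, at adjusted p values of 0.0559 for Scd2, Hint2, Bhmt, Sntb1 and Ppap2b, 0.0565 for Plxnb1 and 0.0817 for Bnip3l. Without Great Basin creosote 1 the calls of Hint2 (0.0606), Plxnb1 (0.101), Ppap2b (0.152) and Sntb1 (0.095) were lost too. Bnip3l was lost without any of 10 animals, all except Great Basin creosote 2 and 4, Great Basin juniper 4 and Mojave creosote 2, 3 and 4, with adjusted p values up to 0.101. Scd2 was lost without any of 12, all except Great Basin creosote 2 and 4 and Mojave creosote 3 and 4, with adjusted p values up to 0.148.

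On juniper, Mojave livers held more of the nucleosome assembly gene Nap1l2, by 1.05 ± 0.15 (SE, n = 4 per group, adjusted p = 0.0457), with within-slide differences from 0.60 to 1.28. Its probe was dim: it was well above background on 4 of 4 arrays of each juniper group, but on 1 Great Basin and 2 Mojave creosote arrays. The Great Basin juniper mean (-0.59) lay close to those of the creosote groups (-0.63 and -0.71). Over the alternatives the difference ran from 0.74 to 2.57. Limma called 3 genes, 1 higher and 2 lower. The others, named after their values were seen, were a T-cell receptor beta-chain probe (-0.49 ± 0.07) and an unnamed transcript tag (-0.71 ± 0.10). Proliferation genes were higher in Mojave animals as a list, with a median of 0.33, slide medians between 0.002 and 0.64 and an adjusted p of 2.99e-12 by camera. Of these, 0 of 21 passed over all genes and 10 were higher adjusted over the list alone, and the list call was lost with an estimated correlation (adjusted p = 0.259). The other lists called on juniper were ribosomal proteins (median -0.13, 0 of 72 past the threshold, 1 lower adjusted over the list alone, adjusted p = 1.57e-07, adjusted p = 0.419 with an estimated correlation) and 3 more with 0 members past the threshold over all genes. These were urea cycle genes (median 0.11, 1 higher adjusted over the list alone, adjusted p = 0.0211), oxidative phosphorylation (median -0.06, 0 adjusted over the list alone, adjusted p = 0.0233) and complement and coagulation (median -0.13, 0 adjusted over the list alone, adjusted p = 0.0211). For these 3 lists the values were adjusted p = 0.419, adjusted p = 0.419 and adjusted p = 0.611 with an estimated correlation. Fry called 0 lists on juniper. With median centring the medians of ribosomal proteins and oxidative phosphorylation turned positive, and neither list was called. The call of Nap1l2 was lost without any of 11 animals, all except Great Basin creosote 3 and 4, Mojave creosote 1 and 2 and Mojave juniper 2. Its adjusted p then lay between 0.063 without Mojave creosote 4 and 0.187 without Great Basin juniper 2, and it was 0.468 without slide 1. A fit with slide as a block called 1 gene, and 0 were called with replicate number as a block or with the processed signals. Other settings called more, mostly higher in Mojave: 72 with only the 8 arrays compared (54 higher and 18 lower) and 26 with array weights (16 higher and 10 lower). On creosote the fit of only the 8 arrays compared lowered the count, from 19 to 3. The count of 3 fell to 0 without Great Basin creosote 1 or 2, any Great Basin juniper animal, Mojave creosote 3 or 4, or Mojave juniper 1, 3 or 4, and rose to 6 without Great Basin creosote 3 or Mojave creosote 1, 5 without Mojave creosote 2 and 15 without Mojave juniper 2.

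Averaged over the diets, Mojave livers held less of the ribosomal protein gene Rpl24 (-1.37 ± 0.19, SE, n = 8 per population, adjusted p = 0.0242), less Bhmt (-0.94 ± 0.12) and less of the ubiquitin protease Usp49 (-0.77 ± 0.10). Differences were smaller in Ppap2b (-0.59), the DNA repair gene Mpg (-0.38) and Gpr116 (-0.37). Rpl24 was split within Mojave juniper, at 0.438 in animal 2 against -0.772 to -0.742 in the others. The Great Basin means of Rpl24 were 0.652 on creosote and 0.965 on juniper. A lower signal can also come from a sequence difference under the probe, which was not examined, so it need not mean less transcript. Limma called 9 genes, 1 higher and 8 lower in Mojave, and 8 with slide as a block. The count was 42 with median centring (2 higher and 40 lower), 51 without the sex term (14 higher and 37 lower) and 0 with the processed signals. Camera called the proliferation list (0 of 21 past the threshold, 5 higher adjusted over the list alone, median 0.16, adjusted p = 9.5e-07). It also called the complement and coagulation list (0 of 30, 0 adjusted over the list alone, median -0.12, adjusted p = 0.0123). Both were lost with an estimated correlation (adjusted p = 0.888 for each). A second probe did not show the difference of Bhmt (-0.02) or Ppap2b (-0.11), and that of Mpg gave -0.30. Bhmt and Usp49 were lost without Great Basin juniper 3 (adjusted p = 0.0619 and 0.0618), and Rpl24 without Great Basin juniper 3 or 4, Mojave creosote 4 or Mojave juniper 3 or 4 (adjusted p = 0.0672, 0.0691, 0.0553, 0.0991 and 0.12). Mpg, Ppap2b and Gpr116 were each lost without Great Basin creosote 1 or 3, Great Basin juniper 3 or 4, Mojave creosote 4 or Mojave juniper 3 or 4, with adjusted p values up to 0.133. Ppap2b was lost without Mojave juniper 1 as well (0.0513), Gpr116 without Mojave creosote 1 or 2 (0.0625 and 0.0536), and Mpg without Great Basin juniper 1 or 2, Mojave creosote 1 or Mojave juniper 1 (0.0534, 0.0904, 0.0635 and 0.0506). Without slide 1 the count was 0. The count of 9 was 20, 86 and 18 without Great Basin creosote 1, 2 and 4, 20, 0 and 3 without Great Basin juniper 1, 3 and 4, 18, 34 and 4 without Mojave creosote 2, 3 and 4, and 5, 21, 3 and 4 without Mojave juniper 1, 2, 3 and 4.

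The interaction asks whether the diet difference itself differed between the populations. The genes with the smallest p, none past the threshold, were Asf1a, whose diet difference was more negative in Mojave animals by -0.86 ± 0.12 (SE, n = 4 per group, adjusted p = 0.0541). The others were the prefoldin subunit Pfdn5 (0.71 ± 0.11, adjusted p = 0.0541), Plxnb1 (-0.97 ± 0.16, adjusted p = 0.0568), Gcsh of glycine cleavage (0.75 ± 0.13, adjusted p = 0.0568) and the olfactory receptor Olr875 (0.62 ± 0.11, adjusted p = 0.062). Second probes did not show the difference for Gcsh (0.09) and Plxnb1 (-0.14), and that of Asf1a gave a smaller one (-0.47). Limma called 0 of 26472 genes, although 3435 had an unadjusted p under 0.05, where 1324 would by chance. Other fits gave 14 calls with slide as a block, 1 with replicate number as a block, 1 with trend and robust settings, 13 with array weights and 67 without the sex term. Scaling between arrays and the mean of all probes gave 10 each, and median centring gave 2417, 126 positive and 2291 negative. Leaving out 1 animal gave 331 calls without Great Basin creosote 4, 33 without Mojave creosote 4, 20 without Mojave creosote 3, 7 without Mojave juniper 2, and 6 without Great Basin creosote 2 or Mojave creosote 2. As lists, proliferation genes (median -0.51, 0 of 21 past the threshold, 5 lower adjusted over the list alone) and ribosomal protein genes (median 0.16, 0 of 72 past the threshold, 2 higher adjusted over the list alone) differed by camera. Each had an adjusted p of 0.000253, and each with an adjusted p = 0.762 with an estimated correlation. Fry called 0 lists for the interaction, and the ribosomal list turned negative with median centring (-0.394).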

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

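The tests of array position and of the sides of the slide were chosen only after the diet result was seen, and the fits without slide 1 after the dim arrays were seen.

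Single animals lay far from the other 3 of their group in 17 of 346 sets of group values tested with Dixon's criterion. Chance gives such a gap in about 1 in 20 groups, or 17.3 of the 346, so the number itself needs no explanation. The values are log2 ratios of the animal to the pool, and for lists the mean of the members. Among genes, Acmsd was 0.808 in Great Basin creosote 3 against 0.364 to 0.397 in the others, Gys2 was -0.047 in Great Basin juniper 1 against 0.621 to 0.691, and Gys2 was 0.006 in Mojave creosote 3 against -0.892 to -0.828. Bex4 was -1.324 in Mojave juniper 2 against -0.795 to -0.729, Igfbp3 was -0.098 in Mojave juniper 4 against -1.54 to -1.402, and Cfi was 0.681 in Great Basin juniper 2 against -0.742 to -0.585. Chuk was -0.319 in Great Basin creosote 2 against -0.794 to -0.737, Rpl24 was 0.438 in Mojave juniper 2 against -0.772 to -0.742, and Gpr116 was -0.007 in Mojave creosote 3 against -0.197 to -0.18. Among lists, UDP-glucuronosyltransferases were at -0.369 in Mojave creosote 2 against 0.035 to 0.093, carbonyl-reducing and aldehyde-oxidising enzymes at -0.076 in Great Basin creosote 4 against 0.033 to 0.05, and drug transporters at 0.04 in Great Basin juniper 4 against -0.025 to -0.014. Acute phase genes were at 0.431 in Great Basin juniper 2 against -0.123 to -0.032, heat shock genes at 0.261 in Great Basin juniper 1 against 0.01 to 0.027, and proteasome genes at 0.184 in Mojave juniper 4 against 0.058 to 0.077. Endothelial markers were at 0.015 in Great Basin creosote 4 against 0.079 to 0.082, and neutrophil markers at 0.047 in Mojave juniper 1 against -0.086 to -0.069.

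The diet difference of 2 lists differed between the populations by the camera test of the interaction, with medians of -0.512 for proliferation and 0.157 for ribosomal proteins. Both were lost with an estimated correlation (adjusted p = 0.762) and with fry (adjusted p = 0.306). As many called lists were given by 75 of 100 divisions of the arrays, the real one included (2, highest other 13). These divisions exchanged animals between the diets within a population, so the diet difference can enter their interaction. They cannot decide whether chance gave the 2 lists, and chance is not excluded.

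Other divisions of the same arrays show how often such counts arise, at shares that were not adjusted for the number of counts examined. For the diet effect in Great Basin, 1 of 35 divisions gave as many genes, the real one (1052, highest other 2). For Mojave it was 1 of 35 as well (2531, highest other 1), so chance is an unlikely source of either count. For the averaged diet effect chance is unlikely too, with 1 of 100 (3199, highest other 1697). For the averaged population effect 2 of 100 gave at least 9 genes, the real one and 1 with 24. That count of 9 was 0 without Great Basin juniper 3, without slide 1, with the processed signals and in male animals, so chance is not excluded for it. The 3 genes of the population effect on juniper were reached by 1 of 35 divisions (highest other 2), although most animals left out singly brought that count to 0. Chance cannot be excluded for the 19 genes of the population effect on creosote, which 4 of 35 divisions reached (highest other 771). The interaction had 0 genes by limma (3435 at an unadjusted p under 0.05, and 0 to 67 by other tools except 2417 with median centring). Any division reaches 0, so the 100 of 100 that did (highest other 36) decide nothing. The division of the creosote arrays with 771 genes gave several times the real count of 19, which points to a structure of the samples. The real count was 21 with slide as a block, 19 with replicate number as a block, 283 without the sex term and 0 without slide 1. The divisions themselves were fitted only with the sex term, on all slides and without a block, so the cause stays open. For called lists, the 12 of the Mojave diet effect were reached by 1 of 35, the real one (highest other 8). The 14 of the averaged diet effect were reached by 2 of 100, the real one and 1 other, which also had 14. Chance cannot be excluded for the number of lists of the Great Basin diet effect (11 lists, reached by 6 of 35, highest other 14), of the population effect on juniper (5 lists, 8 of 35, highest other 10), and of the averaged population effect (2 lists, 53 of 100, highest other 7). On creosote the population effect had 0 lists, which 35 of 35 divisions reach by construction (highest other 11), so nothing is decided there either.

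The first pattern weighed was the large number of genes that differed between the diets. A steady gradient along the slide would make the Mojave differences, between neighbouring positions, 0.33 of the Great Basin ones, but over the 3199 genes of the averaged effect the median ratio was 1.3 (quartiles 0.797 and 2.356), which argues against a gradient as the cause. A difference between the sides of the slide cannot be told apart from the diet, since 0 of 4 slides held both diets on 1 side. A response to the diets stays open as the biological explanation.

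The second pattern was the rise from 19 to 283 genes for the population effect on creosote when the sex term was left out. With the female label shuffled within groups, 2 of 100 assignments gave as few genes as the real sexes. The sex term itself called 1 of 26472 genes, and 1159 had an unadjusted p under 0.05 where 1324 would by chance, which gives no sign of widespread differences between the sexes. Expression differences between the sexes, which the all-male Mojave creosote group would bring into the comparison, therefore stay open. A loss of precision from the added term stays open beside it, since the median over the shuffled assignments was 56 genes (14 to 459), between both counts. A difference between the populations stays open as well. It cannot be told apart from position, since on each slide Great Basin creosote lay at position 1 and Mojave creosote at 2.

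The third pattern was the rise to 3127 genes, 2941 of them lower in Mojave, for the same comparison with median centring. Over 5 equal bins of intensity the median difference spanned 0.558, from 0.08 in the dimmest to -0.479 in the brightest bin, while with loess these medians lay between 0.006 and -0.066. So a dye ratio that varies with intensity and that centring leaves in may account for it. Single arrays mattered too: without Mojave creosote 1, 2, 3 or 4 the count was 1547, 987, 3576 or 3838. No biological explanation was tested for the difference between both methods.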

How the results depend on the processing

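The fits without slide 1, and the list tests with slide or replicate number as a block, were chosen only after the data were seen. Where a cause is not given below, the cause was not tested.

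Of 208 gene results, 75 kept their direction and their side of the threshold in each alternative run. Over 6830 gene values under alternatives, without 2 that repeat others by construction, 6074 did so, 722 were no longer past the threshold, 33 newly passed and 1 reversed, Rpl19 in the Mojave diet effect with median centring (-0.08). With median centring 3 list results reversed in the direction of the camera test, given here with medians over the members measured on all 16 arrays: ribosomal proteins (-0.251, adjusted p = 0.0203) and oxidative phosphorylation (-0.099, adjusted p = 0.429) in the Mojave diet effect, and ribosomal proteins in the interaction (-0.394, adjusted p = 0.000304). The medians of 4 more lists changed sign without a reversed test: lipogenesis (-0.051) and gluconeogenesis and glycogen (-0.005) in the Mojave diet effect, and ribosomal proteins (0.005) and oxidative phosphorylation (0.009) in the population effect on juniper. Those 4 lists were no longer called. Over the 5 main comparisons camera called 30 lists, 4 with an estimated correlation, and between 23 and 32 in the other alternatives. The 4 were the proteasome, urea cycle and hepatocyte lists in the Great Basin diet effect and the proteasome in the Mojave diet effect. Quantile normalisation of the mean intensities leaves ratios as they are, so it tests nothing here.

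The count of the Great Basin diet effect was 152 in male animals and 386 without slide 1, both with fewer animals, and 122 with a difference of at least 1 on the log2 scale, which asks for more by construction. The Mojave count was 1633 with the processed signals and with the series values, which are the same ratios, 4749 with median centring, 1094 with the Cy5 channel alone, 1079 in male animals, 1062 with only the 8 arrays compared and 248 with a difference of at least 1. The averaged diet count was 1254 in male animals, 2112 without slide 1 and 138 with a difference of at least 1.

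The count of the population effect on creosote was 0 with the processed signals, the series values, an offset of 0 and without slide 1, 1 with Cy5 alone, 3 with the 8 arrays compared, 5 in male animals and with a difference of at least 1, 29 with the mean of all probes, 283 without the sex term and 3127 with median centring. On juniper it was 0 with the processed signals, the series values, Cy5 alone, the filter on all 16 arrays, the mean of all probes, male animals, replicate number as a block, trend and robust settings, and without slide 1. It was 1 with an offset of 0, with slide as a block and with a difference of at least 1, 26 with array weights and 72 with the 8 arrays compared. The averaged population count was 0 with the processed signals, the series values, male animals and without slide 1, 1 with a difference of at least 1, 2 with Cy5 alone, 15 with the mean of all probes, 16 with trend and robust settings, 20 with replicate number as a block, 42 with median centring and 51 without the sex term. The interaction, with 0 genes, gave 1 with replicate number as a block and with trend and robust settings, 10 with scaling between arrays and with the mean of all probes, 13 with array weights, 14 with slide as a block, 67 without the sex term and 2417 with median centring.

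Leaving out each animal in turn gave 627 to 1235 genes for the Great Basin diet effect, 1585 to 2749 for Mojave, 2472 to 3169 for the averaged diet effect, 0 to 473 and 0 to 15 for the population effect on creosote and on juniper, 0 to 86 for its average and 0 to 331 for the interaction. Replicate numbers do not pair the animals: residuals of arrays that share a number had a mean correlation of 0.003, and a fit with that number as a block called 939 and 2391 genes for the diet effects. Signal over background limits the dimmer transcripts: 49.2% of probes were well above background on slide 1, and 8 called genes were above background on no array of 1 of the groups compared.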

Other observations

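The gene families below were chosen only after the averaged diet result was seen, and the tests of the relations between lists were chosen before it.

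Of 62 genes of ubiquitin conjugation and removal, 14 were called for the averaged diet effect, and all 14 were lower on creosote (22.6%, against 16.3% of all genes with a symbol). No enrichment test was run for the families of this paragraph. Olfactory receptors were called in 70 of 933 (43 higher and 27 lower, 7.50%). Solute carriers were called in 29 of 238 (10 higher and 19 lower), translation initiation factors in 7 of 39 (1 higher and 6 lower), Rab GTPases in 9 of 48 (4 higher and 5 lower) and keratins in 3 of 19 (all lower).

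Limma called 1 gene between the sexes, an unnamed transcript, singled out after its values were seen. It was lower in females by -2.43 ± 0.12 (SE, 6 females and 10 males, adjusted p = 4.93e-08), with a female mean of -1.82 (SD 0.12, highest -1.64) and a male mean of 0.41 (SD 0.38, lowest -0.25). The next adjusted p was 0.101, and 1159 genes had an unadjusted p under 0.05 where chance gives 1324.

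If the difference of the proteasome genes between the diets belonged to a shared stress programme, proteasome and heat shock genes may vary together between animals of a group. Which diet would have changed them cannot be told without a group on chow alone. Over 16 animals, after group and sex were removed, Pearson's r was 0.474 (2-sided permutation p = 0.0639, adjusted 0.128) and Spearman's rho 0.382 (permutation p = 0.144, adjusted 0.288), and r was 0.454 without the 2 animals farthest from the median. For proteasome and NRF2 target genes r was 0.366 (permutation p = 0.166, adjusted 0.166) and rho 0.265 (permutation p = 0.322, adjusted 0.322), and r was 0.441 without the 2 farthest animals. Neither of the 2 relations passed the threshold, and among 37 lists these ranked 5 and 11 by r with the proteasome, where the median r was 0.219. The permutations treated the 16 residuals as exchangeable, although 11 degrees of freedom remained after group and sex were removed. The permutation p values may therefore be too small. Whether the proteasome genes vary together with either list was not decided by 16 animals.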
